A study of Mus musculus with 8 samples.

How the data were processed

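Heart RNA from 8 male mice aged 12 weeks was measured, 4 mice overexpressing PKR2 and 4 wild-type (WT) mice, each on its own 1-colour array of mouse oligonucleotide probes. Per the labels' protocols, total RNA was extracted with Tri-Reagent and labelled with the dye Cy3. Per the file headers, the scanned images were read with Agilent Feature Extraction 9.5.1.1, which flagged outlying spots, subtracted the background and removed spatial trends within each array, and the probes' positions refer to the mouse build mm8. The deposited scanner values used here are spot intensity on a linear scale, not yet normalized between arrays. The authors' deposited value table holds intensity already normalized between arrays, rounded to whole numbers, by a method not given in the sources used here. It served as an alternative. Its column medians lie between 139 and 144, and over its bright probes (value over 2000) its logarithm correlated with that of the scanner's median signal at r of 0.999 to 1.00 on each array (across probes, which are not replicates). It was read as linear, uncentred signal; the normalization behind it stays unknown.

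For each array the processed signal was taken to log2 and the 75th percentile over the array's non-control probes was subtracted, so a level of 0 is that percentile. Control spots and spots with outlier flags were left out, saturated spots were kept, and spots of 1 probe were averaged. Each array held 43379 non-control spots of 41174 probes. A probe was tested where it was well above background on at least 3 of the 4 arrays of 1 group or more, which kept 22715 probes, and 97 further detected probes were left out for having no unflagged spot on some array. Probes were named through their transcript accession (24375 probes) or, failing that, their symbol or a synonym (8635 probes) in a RefSeq gene table of assembly GRCm38.p6, used for names alone; 1698 probes kept the file's name and 6466 had no symbol. A gene with several tested probes was represented by the probe with the highest mean signal, chosen without regard to group, and a probe without a symbol was its own feature, giving 15680 features, 13934 of them with a symbol.

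Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all features at a threshold of 0.05. Adjusted p-values of single genes in the text come from limma. Data were handled with the package data.table (version 1.17.8). A set of 38 gene lists, 22 for pathways and 16 for cell types or tissues, was tested with camera at a preset correlation of 0.01, adjusted over the 38 lists, with camera at a correlation estimated within each list and with fry beside it. A list's score on an array is the mean over its tested members of the log2 signal minus that gene's mean over the 8 arrays. Scores and single genes given with an exact p were compared by a two-sided exact permutation test over all 70 relabelings of 4 against 4, whose smallest possible p is 0.0286. For a probe not well above background on any array of a group, only a bound on the fold is given: the brighter group's mean was set against the dimmer group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

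The group of each mouse, the fit, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The rule names Prokr2, Prokr1, Prok1 and Prok2; up to 12 genes per direction past the threshold with the largest change, filled up to 8 per direction by smallest p where fewer pass, skipping predicted genes; the 4 members with the smallest p of each list that passed and of the hypertrophy, calcium handling, endothelial junction, extracellular matrix and cardiomyocyte lists; up to 3 members past the threshold in other lists; and Gapdh, Actb and Hprt as control genes. Some genes that the rule names are not reported here. A gene named outside the rule is said to be so. The alternatives were normexp background correction with an offset of 50, quantile and median normalization, the authors' deposited values, looser and stricter probe filters, other probe-to-gene rules, slide, array position and extraction run as blocks or covariates, another variance model, array weights, 2 other thresholds and leaving out each array. Added after the data were seen were normexp after bringing the arrays to a common level, leaving out slide 6, scan range as a block and the adipocyte score as a covariate.

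The 8 arrays lay on 6 slides, and slides 5 and 6 each held 1 WT and 1 PKR2 array. With slide as a fixed block a difference therefore rests on the arrays of slides 5 and 6 alone. All 4 PKR2 arrays and WT 1 sat at position 4 of their slide. With array position as a covariate, as with arrays at position 4 only, a difference therefore sets the PKR2 arrays against WT 1 alone. WT 2, WT 4 and PKR2 4 were scanned at a single low range and the others over an extended range. WT 3, PKR2 2 and PKR2 3 shared an extraction run. Extraction run here means the hour at which Feature Extraction read the images, per the file headers. It does not mean a batch of RNA extraction. Replicate numbers only name the arrays and pair nothing. The procedure was tested on simulated data with the spread of these arrays, with 15680 features and 4 arrays against 4. It recovered 1.43% of 70 changes of 1.5-fold, 34.3% of 70 changes of 2-fold and 93.3% of 60 changes of 4-fold. There were 7 false calls, and 0 calls with no change. A shift of 0.3 (log2) in 1 list was recovered, and 0 lists were called with no shift. Noise was drawn independently for each gene and array, with no correlation between genes and no slide structure. The simulation therefore does not check the list test where genes vary together, as the adipocyte markers do (estimated correlation 0.834).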

Results

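The heart transcriptome of adult male mice overexpressing PKR2 was compared with that of WT mice, with 4 mice per group and 1 array per mouse. PKR2 is read here as prokineticin receptor 2, a G protein-coupled receptor for the secreted peptides prokineticin 1 and 2, encoded by Prokr2. The share of spots well above background ran from 48.3% (WT 2) to 67.1% (PKR2 1), and the 75th percentile of processed signal from 40.9 (WT 2) to 770 (PKR2 1). Log2 levels correlated between arrays (across features, which are not replicates) at r of 0.971 to 0.987 within WT, 0.972 to 0.991 within PKR2 and 0.965 to 0.988 between groups. Levels below are log2 signal relative to each array's 75th percentile, given as mean ± SD with n = 4 arrays unless stated, and differences are PKR2 minus WT. The precision is limited by the number of arrays: the 95% interval of a feature's difference reached a median of 0.48 to either side.

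The first question was whether the receptor's own transcript was higher in the overexpressing hearts. The single Prokr2 probe (chromosome 2, 132062775 to 132062834, mm8) was not well above background on any of the 8 arrays. Its signal was -6.02 ± 0.62 in WT and -6.38 ± 0.67 in PKR2 hearts, a difference of -0.35 (exact permutation p = 0.457, two-sided), and no fold is given because both groups were below background. The probe need not detect a transgene from another species or one lacking the probed stretch, so it does not check the genotype labels. Of the other members of the system, Prokr1 and both Prok2 probes were also not well above background on any array. Prok1, which encodes prokineticin 1, was above background on all 8 arrays with 1 of its 2 probes, at -3.23 ± 0.55 in WT and -3.04 ± 0.19 in PKR2 hearts, a difference of 0.18 (exact permutation p = 0.600), and on none with the other.

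Across the transcriptome the clearest single-gene difference was in Anks1, which encodes an ankyrin repeat and SAM domain protein that acts downstream of receptor tyrosine kinases. Its level was 3.57 ± 0.11 in WT and 6.03 ± 0.59 in PKR2 hearts, a difference of 2.46 (SE 0.27, 5.50-fold), and the lowest PKR2 array (5.15) lay above the highest WT array (3.72). The 1 Anks1 probe lies on chromosome 17, 27789971 to 27790030 (mm8). At limma adjusted p = 0.0747 it missed the threshold over all 15680 features and was the 1 feature with an adjusted p under 0.1. Within the slides that held both groups the Anks1 difference was 1.60 on slide 5 and 2.56 on slide 6. With slide as a fixed block, which rests on the same arrays, it was 2.08 (adjusted p = 0.50). Anks1 passed the threshold when only probes above background on all 8 arrays were tested (adjusted p = 0.0351) and with slide as a random block (2.33, adjusted p = 0.0317). It also passed with a trended robust variance (adjusted p = 0.0238) and without PKR2 3, whose Anks1 level was the lowest of its group (2.75, adjusted p = 0.000821). These were the only 4 of 27 refits in which it passed. Leaving out any other array gave a limma adjusted p from 0.181 (without PKR2 2) to 0.453 (without PKR2 4).

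**Figure D1:**
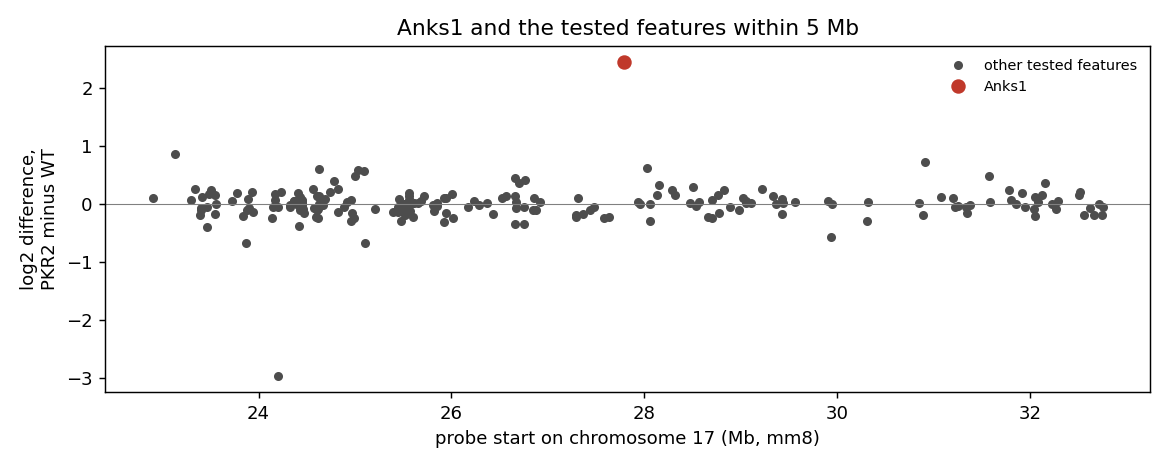
Difference between PKR2 and WT hearts (y axis, log2) of Anks1 and of the 205 other features tested within 5 Mb of it, against probe start on chromosome 17 in Mb (x axis, mm8). Anks1 stands at 2.46, and the single point near -3 is Pgp (-2.98), which is low on array PKR2 1 alone.

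No feature passed limma's adjusted p of 0.05, while 371 features had an unadjusted p under 0.05, 150 higher and 221 lower in PKR2 hearts, against 784 expected by chance. The groups did not overlap in 245 features, 1.56% of those tested, where chance gives 2.86%. Of the genes of smallest p with higher values in PKR2 hearts, none passed. After Anks1 the brightest of them was Myh7, the slow beta myosin heavy chain of fetal and stressed ventricle, at 5.77 ± 0.16 in WT and 6.46 ± 0.28 in PKR2 hearts (difference 0.69, SE 0.18, adjusted p = 1). Within slides the Myh7 difference was 0.39 on each of slides 5 and 6, and hence also 0.39 with slide as a fixed block. With the adipocyte score as a covariate it was 0.40 (SE 0.19, adjusted p = 1). Another 5 were dim. Tas2r118 and Prdm10 were not well above background on any WT array and at least 1.26-fold and 1.56-fold higher in PKR2 hearts (each adjusted p = 1). Col12a1 (0.85), Sec16b (0.58) and Creb3l3 (1.04) were above background on 1, 3 and 2 WT arrays. All 5 turned to lower values under normexp background correction, from -0.48 for Sec16b to -0.64 for Tas2r118. The offset of that correction compresses low signals unevenly between arrays, most on those of the single low scan range. All 5 also turned to lower values under normexp after common scaling, from -0.17 for Col12a1 to -0.29 for Prdm10. Uneven array levels alone therefore do not account for the turn in full, and its cause was not tested.

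**Figure D2:**
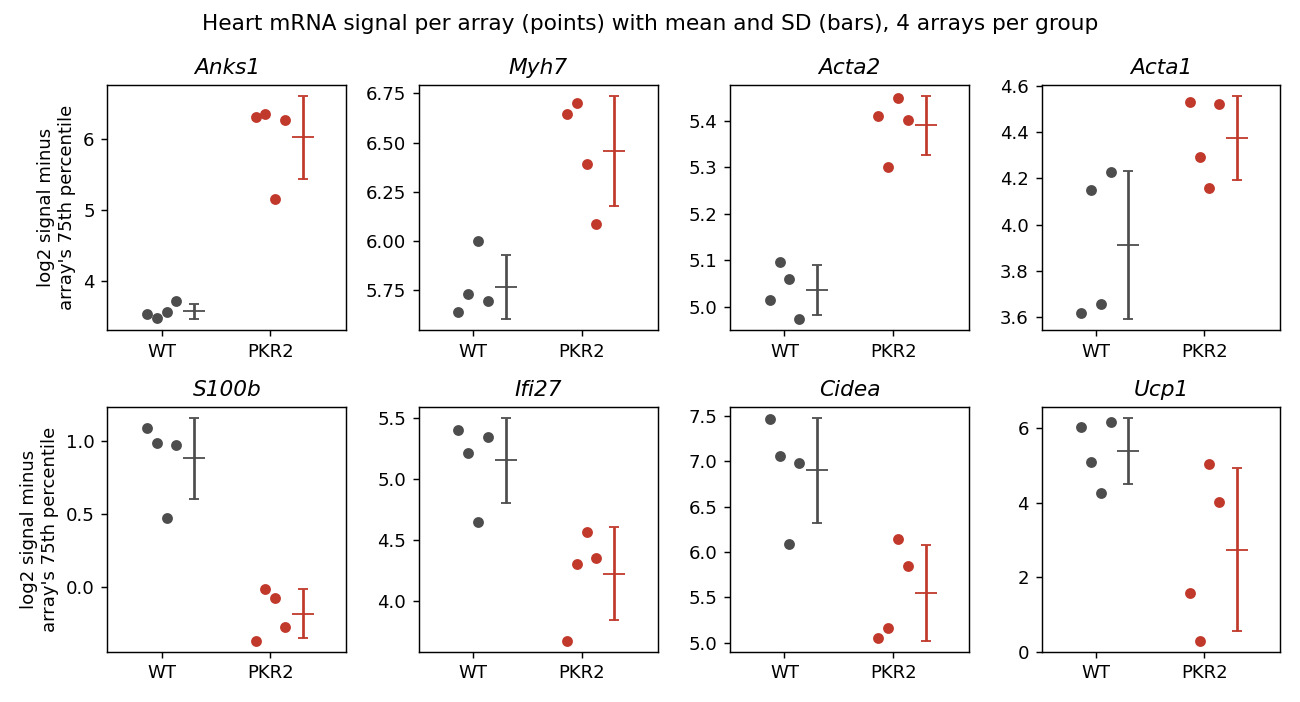
Signal of 8 genes per array (points, 4 per group), with the group mean and SD as bars; the y axis is log2 signal minus the array's 75th percentile, on a separate scale in each panel. Anks1 separates the groups by the widest gap, while Ucp1 is low in PKR2 1 and PKR2 2 (1.58 and 0.30) and within or near the WT range in PKR2 3 and PKR2 4 (5.04 and 4.01).

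Among genes with lower values in PKR2 hearts, the smallest p belonged to S100b, a calcium-binding protein used as a marker of Schwann cells and also present in adipocytes. S100b was 0.88 ± 0.28 in WT and -0.18 ± 0.17 in PKR2 hearts, a difference of -1.06 (SE 0.18, adjusted p = 1), and lower in PKR2 within slide 5 (-0.55) and slide 6 (-1.24). Cidea, a lipid droplet protein of brown adipocytes, differed by -1.35 (SE 0.33), the brown adipose transcript Lncbate1 by -1.64 (SE 0.34) and the apolipoprotein gene Apoc1 by -2.15 (SE 0.55). Apoc1 was lowest in PKR2 1 and PKR2 2 (0.44 and 0.36), the arrays with the lowest adipocyte scores, against 2.03 and 2.41 in PKR2 3 and PKR2 4. With the adipocyte score as a covariate Apoc1 differed by -0.85 (SE 0.27) and Cidea by -0.63 (SE 0.25). Cidea is itself 1 of the 15 genes averaged into that score, so its difference shrinks partly by construction. The remaining 4 were Agmo (-0.89, SE 0.19), Itpka (-1.24, SE 0.27), Cd274, which encodes the immune checkpoint ligand PD-L1 (-0.81, SE 0.18), and Cpn2 (-1.74, SE 0.38). The same covariate brought Itpka to -0.73 (SE 0.25) and Cpn2 to -1.02 (SE 0.36). With it S100b stood at -0.92 (SE 0.23), Agmo at -0.68 (SE 0.24), Cd274 at -0.71 (SE 0.24) and Lncbate1 at -1.195 (SE 0.40). None of these 8 passed the threshold (limma adjusted p = 1 for each). The control genes differed by 0.17 (Gapdh, SE 0.17), -0.055 (Actb, SE 0.21) and -0.0072 (Hprt, SE 0.30), with the signs of Actb and Hprt turned under normexp and quantile normalization.

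The next question was which gene programmes shifted as groups. Of the 38 lists, 6 passed camera at the preset correlation, 1 higher and 5 lower in PKR2 hearts, and none passed with a correlation estimated within the list (smallest adjusted p = 0.325) or by fry (smallest adjusted p = 0.878). The list called higher was the hypertrophy and fetal gene programme, transcripts that mark cardiac growth and stress. Of its 24 tested members 19 had higher and 5 lower values in PKR2 hearts, with a median difference of 0.15 (adjusted p = 0.000237 at the preset correlation, adjusted p = 0.325 with an estimated correlation). Its score was higher in all 4 PKR2 arrays than in any WT array (exact permutation p = 0.0286, the smallest that 4 against 4 can give, n = 4). That p was not adjusted over the 38 lists. The gap was narrow, from -0.0129 in WT 2 to 0.0004 in PKR2 4. No member passed over all features or adjusted over the list alone (smallest adjusted p = 0.0830, for Myh7). Besides Myh7, smooth muscle actin Acta2 differed by 0.36 (SE 0.13), skeletal actin Acta1 by 0.46 (SE 0.19) and slow skeletal troponin I, Tnni1, by 0.25 (SE 0.15), the last a dim probe whose sign turned under normexp (-0.65). The natriuretic peptide genes Nppa and Nppb, outside the naming rule and chosen after their values were seen, differed by 0.059 (SE 0.18) and 0.35 (SE 0.24). The list's median was 0.16 within slide 5 and 0.055 within slide 6, 0.091 without PKR2 1 and 0.094 without WT 3. Under normexp it was 0.47 and under normexp after common scaling 0.27. Its call ended with slide as a fixed block (0.13, adjusted p = 0.190), a fit that rests on slides 5 and 6 alone. It also ended with array position as a covariate and with arrays at position 4 only (0.16 in both). Those fits set the PKR2 arrays against WT 1 alone.

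Lists of the contractile apparatus and its calcium supply had small medians. The sarcomere list (25 genes, 19 higher) had a median of 0.064 (adjusted p = 0.0768) and the cardiomyocyte markers (19 genes, 14 higher) one of 0.080 (adjusted p = 0.165). Both lists were called under quantile normalization and neither under median scaling. The cardiac actin Actc1 differed by 0.25 (SE 0.17), titin, Ttn, by 0.22 (SE 0.16), the Z-disc gene Ldb3 by 0.20 (SE 0.18) and the muscle creatine kinase Ckm by 0.18 (SE 0.17). With the adipocyte score as a covariate Actc1 differed by 0.13 (SE 0.23) and Ldb3 by 0.016 (SE 0.23). Leaving out 1 array took Ldb3 and Ckm down to 0.092 and 0.093, Ttn to 0.12 and Actc1 to 0.14. Calcium handling (22 genes) was split 11 against 11, with a median of 0.0098 and a mean of -0.0084 (adjusted p = 0.773). In it the phosphatase inhibitor gene Ppp1r1a differed by -1.05 (SE 0.29), the calcium channel subunit Cacnb2 by 0.45 (SE 0.16), calsequestrin 2, Casq2, by 0.25 (SE 0.16) and triadin, Trdn, by -0.39 (SE 0.30). Ppp1r1a moved with the fat markers: with the adipocyte score as a covariate its difference was -0.49 (SE 0.27), while that of Trdn was -0.83 (SE 0.34). Leaving out 1 array, Trdn ran from -0.58 to -0.14. No member of these 3 lists passed, over all features or adjusted over the list alone.

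The stroma and vessels did not pass as groups in the main fit either. The extracellular matrix and fibrosis list (43 genes, 27 higher) had a median of 0.086 (adjusted p = 0.0603). In it thrombospondin 1, Thbs1, differed by 0.50 (SE 0.19), Col5a2 by 0.34 (SE 0.16), Col4a2 by 0.27 (SE 0.20) and the matrix protease Mmp9 by -0.28 (SE 0.17). With 1 array left out, Col5a2 shrank to as little as 0.24, Col4a2 to 0.17 and Mmp9 to -0.16. Over all 27 refits Thbs1 ran from 0.020 to 0.83. The matrix list itself was called in part of these refits. Among them were quantile normalization, the authors' deposited values, slide as a random or fixed block and scan range as a block. It was not called in others, among them median scaling, array weights and array position as a covariate. Genes of endothelial junctions and permeability (30 genes, 16 higher) had a median of 0.027 (adjusted p = 0.689), with the vessel-stabilising ligand Angpt1 at 0.45 (SE 0.27), Vegfa at 0.23 (SE 0.17), the junction protein Esam at 0.22 (SE 0.17) and caveolin 1, Cav1, at -0.40 (SE 0.27). The adipocyte score as a covariate moved Vegfa to 0.42 (SE 0.21), Esam to 0.12 (SE 0.23) and Cav1 to -0.12 (SE 0.34). Leaving out 1 array took Angpt1 down to 0.27, Esam to 0.11 and Cav1 to -0.21. Endothelial cell markers (20 genes) had a median of -0.013, fibroblast markers (16 genes) one of 0.0057 and the angiogenesis list (29 genes) one of 0.0017, with adjusted p of 0.836, 0.529 and 0.348.

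The list with the widest shift was that of adipocyte markers, called lower in PKR2 hearts. All 15 tested members had lower values, with a median of -1.74 (adjusted p = 1.88e-18 at the preset correlation, adjusted p = 0.420 with an estimated correlation, which was 0.834). Adjusted over the list alone, Cidea passed (adjusted p = 0.0400) and the other 14 did not; over all features none did. The thermogenic uncoupling protein Ucp1 differed by -2.65 (SE 0.94), the lipid droplet coat gene Plin1 by -2.18 (SE 0.79) and the adipogenic regulator Pparg by -0.70 (SE 0.25). The score was -2.25 and -1.99 in PKR2 1 and PKR2 2, 0.45 and 0.44 in PKR2 3 and PKR2 4, and -0.29 to 1.37 in WT, a difference in means of -1.68 beside an SD of 1.48 in PKR2 and 0.76 in WT hearts (exact permutation p = 0.143, n = 4). The median of the markers was 0.71 within slide 5 and -0.53 within slide 6. The call ended with slide as a fixed block, which rests on those slides alone (-0.055, adjusted p = 0.790), and with array weights (-0.49, adjusted p = 0.160). It was kept under normexp (-1.12, adjusted p = 5.27e-06) and with slide as a random block (-1.07, adjusted p = 6.44e-07).

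**Figure D3:**
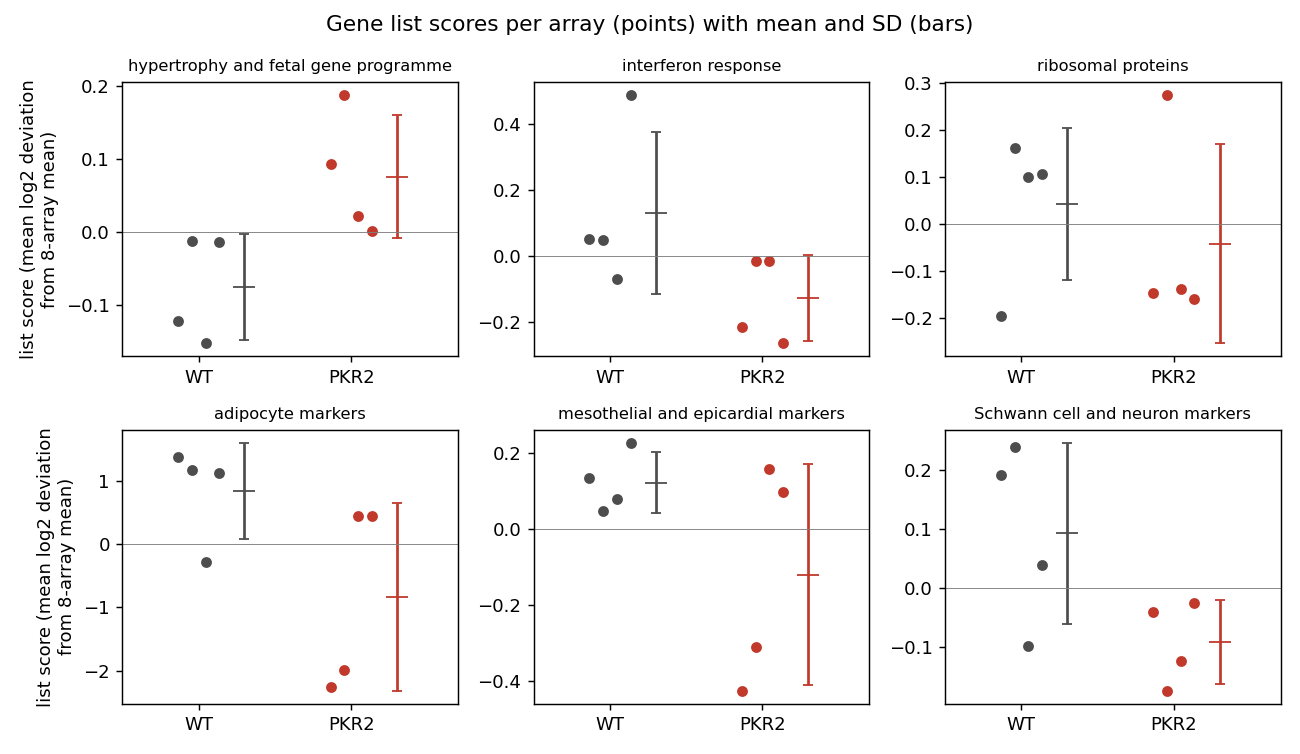
Score of the 6 gene lists that passed camera at the preset correlation, per array (points, 4 per group) with group mean and SD as bars; the y axis is the mean log2 deviation of the list's genes from their 8-array means, on a separate scale in each panel. The hypertrophy scores of the groups do not overlap, by a narrow gap between WT 2 (-0.0129) and PKR2 4 (0.0004). The low adipocyte and mesothelial scores are carried by 2 PKR2 arrays, and the highest interferon score (0.49) by WT 4.

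Of the other 4 lists called lower, mesothelial and epicardial markers had lower values in all 15 genes (median -0.24, adjusted p = 0.000237, adjusted p = 0.807 with an estimated correlation). Among them were Muc16 (-0.30, SE 0.16), the keratin Krt19 (-0.31, SE 0.17), Bnc1 (-0.56, SE 0.33, as little as -0.32 with 1 array left out) and Efemp1 (-0.42, SE 0.30, likewise as little as -0.17). With the adipocyte score as a covariate these were -0.12, -0.019, -0.015 and -0.26 (SE 0.20, 0.18, 0.35 and 0.40). Their scores were lowest in PKR2 1 (-0.43) and PKR2 2 (-0.31), the arrays with the low adipocyte scores, and the call ended without WT 1 (median -0.25, adjusted p = 0.0640), without PKR2 2 (-0.20, adjusted p = 0.0775) or with the adipocyte score as a covariate (median 0.034, adjusted p = 0.466). It also ended under normexp (-0.16, adjusted p = 0.169), under normexp after common scaling (-0.19, adjusted p = 0.0526) and with array weights (-0.013, adjusted p = 0.986), and without PKR2 1 it was kept at -0.14 (adjusted p = 0.0351). Interferon response genes had lower values in 25 of 32 members (median -0.18, adjusted p = 0.000500, adjusted p = 0.807 with an estimated correlation). Ifi27 differed by -0.93 (SE 0.24), the immunity-related GTPases Igtp and Irgm2 by -0.67 (SE 0.21) and -0.60 (SE 0.27), and Oasl1 by 0.43 (SE 0.19), the last with its sign turned under normexp. Irgm2 shrank to as little as -0.30 with 1 array left out, and WT 4 (4.36) stood above the other WT arrays (3.12 to 3.30). The interferon call ended without WT 4 (median -0.054, adjusted p = 0.181), the WT array with the highest score and the one far below the rest of its group in Lars2 and Rn28s1 (4.30 and -3.50, both named after their values were seen), and with the adipocyte score as a covariate (median -0.13, adjusted p = 0.250), in which Ifi27 differed by -0.51 (SE 0.24). It also ended under normexp (-0.098, adjusted p = 0.294), under normexp after common scaling (-0.18, adjusted p = 0.0526) and with no filter on dim probes (-0.18, adjusted p = 0.0531). The same held with array weights (-0.11, adjusted p = 0.326) and with slide 6 left out (-0.089, adjusted p = 0.160). It held too with array position as a covariate and with arrays at position 4 only (-0.069 in both, against WT 1 alone). The median of the interferon genes was -0.027 within slide 5 and -0.47 within slide 6, and with slide as a fixed block -0.25 (adjusted p = 0.00784); that of the mesothelial markers was 0.10, -0.25 and -0.033 (adjusted p = 0.971).

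Ribosomal protein genes had lower values in 38 of 48 members (median -0.088, adjusted p = 0.0497, adjusted p = 0.807 with an estimated correlation), with Rpl9 at -0.22 (SE 0.15), Rpl10a at -0.29 (SE 0.22), Rps16 at -0.16 (SE 0.14) and Rps24 at -0.17 (SE 0.16). With 1 array left out, Rpl9 shrank to as little as -0.11, Rpl10a to -0.10, Rps16 to -0.11 and Rps24 to -0.093. Under normexp the list was called in the opposite direction (median 0.34, adjusted p = 2.45e-07), as it was under normexp after common scaling (0.15, adjusted p = 0.000337). Its median was 0.18 with array position as a covariate, which sets the PKR2 arrays against WT 1 alone, and of 27 refits 10 kept the call. The ribosomal call ended without WT 2 (median -0.048, adjusted p = 0.304), WT 3 (-0.065, 0.192), WT 4 (-0.065, 0.235), PKR2 1 (-0.043, 0.394), PKR2 3 (-0.062, 0.290) or PKR2 4 (-0.053, 0.477). It was kept without WT 1 (-0.17, adjusted p = 0.00883) and without PKR2 2 (-0.21, adjusted p = 1.50e-05). The ribosomal median was -0.27 within slide 5 and -0.29 within slide 6, and -0.27 with slide as a fixed block (adjusted p = 4.05e-05). Schwann cell and neuron markers had lower values in 8 of 11 genes (median -0.16, adjusted p = 0.0497, adjusted p = 0.420 with an estimated correlation). Adjusted over the list alone S100b passed (adjusted p = 0.00188), while the myelin gene Mbp (-0.37, SE 0.23; -0.061, SE 0.27, with the adipocyte score as a covariate) did not. Mbp was lowest in PKR2 1 (0.14, against 0.97 to 1.15 in the other PKR2 arrays), and without that array it differed by -0.14. Of 27 refits 12 kept the call of the list. The Schwann call ended without WT 1 (median -0.12, adjusted p = 0.345), WT 2 (-0.10, 0.304), PKR2 2 (-0.13, 0.250) or PKR2 3 (-0.095, 0.128), and with the adipocyte score as a covariate (-0.073, adjusted p = 0.392). It was kept without WT 3 (-0.089, adjusted p = 0.00792) and without PKR2 4 (-0.055, adjusted p = 0.0189). The Schwann list's median was 0.022 within slide 5 and -0.020 within slide 6, and -0.0062 with slide as a fixed block (adjusted p = 0.971). No member of the mesothelial, interferon or ribosomal lists passed adjusted over the list alone.

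**Figure D4:**
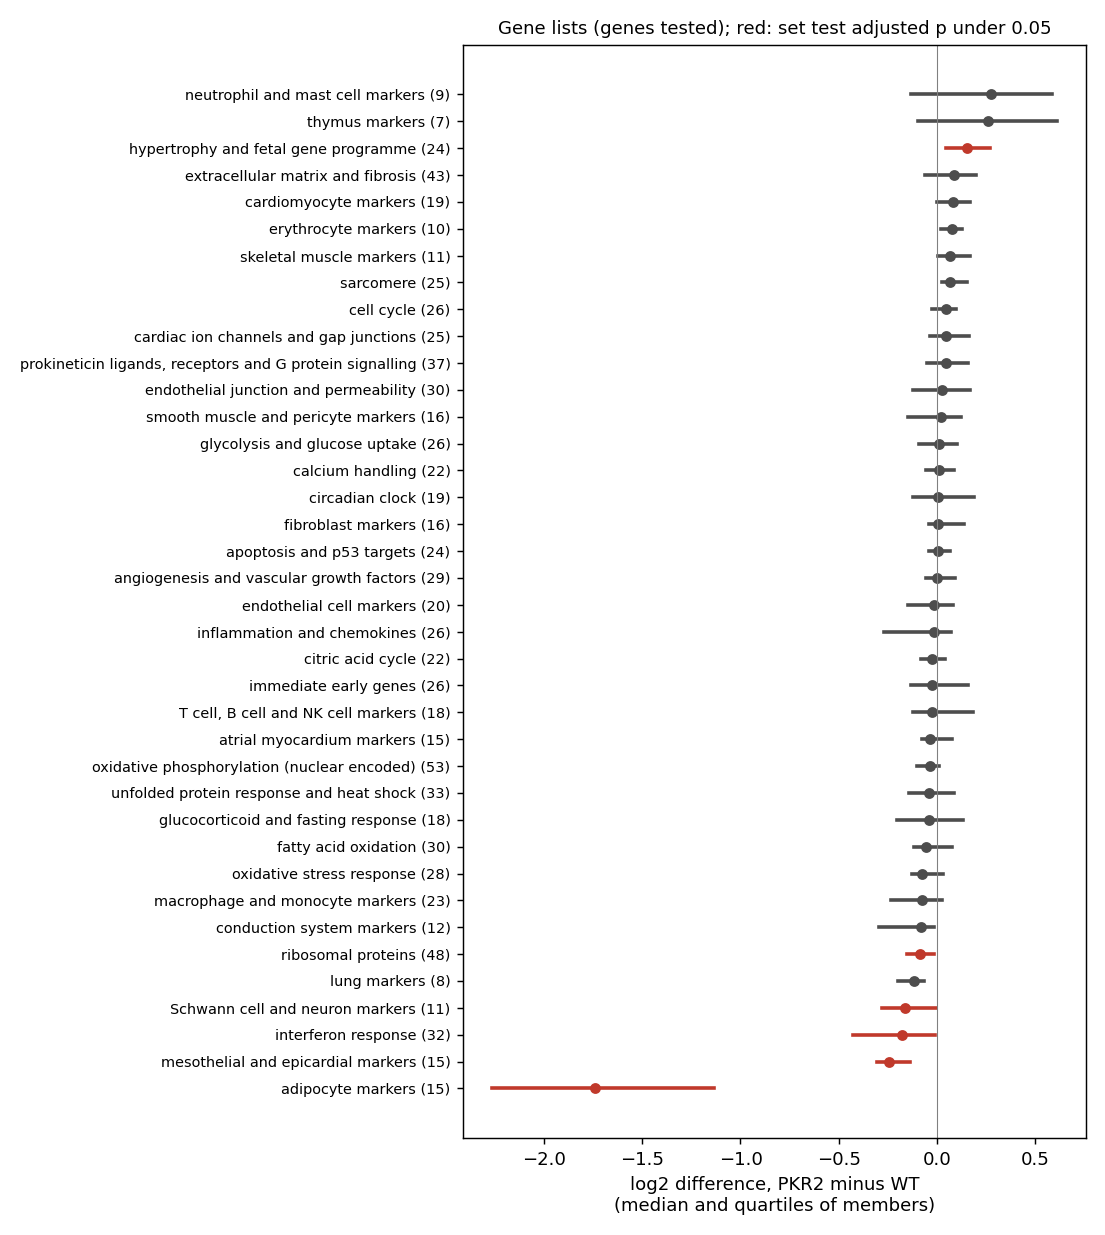
Median difference (points) and quartiles (lines) of the tested members of each of the 38 gene lists, on a log2 axis of PKR2 minus WT, with the number of genes tested in brackets; red marks the 6 lists past camera's adjusted p of 0.05 at the preset correlation. The adipocyte markers stand at -1.74, and the medians of the other 37 lists lie between -0.24 and 0.28.

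Energy metabolism showed no list past the threshold in the main fit. Fatty acid oxidation (30 genes) had a median of -0.056, glycolysis and glucose uptake (26 genes) one of 0.011, oxidative phosphorylation (53 genes) one of -0.036 and the citric acid cycle (22 genes) one of -0.023, with adjusted p of 0.676, 0.911, 0.449 and 0.948. Oxidative phosphorylation was called in some refits, among them slide as a random or fixed block and array weights. Under normexp, as under normexp after common scaling, all of these energy lists were called. The prokineticin and G protein signalling list (37 genes) had a median of 0.043 (adjusted p = 0.587). Macrophage and monocyte markers (23 genes) had a median of -0.079 and those of the conduction system (12 genes) one of -0.084 (adjusted p = 0.160 for each), while inflammation and chemokine genes (26 genes) had a median of -0.016 (adjusted p = 0.344). Markers of blood and atrium varied between arrays without a group difference: the erythrocyte score ran from -0.90 (PKR2 3) to 1.19 (PKR2 2), and the atrial score from -0.31 (WT 1) to 0.25 (PKR2 2), with exact permutation p of 0.886 and 1 (n = 4).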

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

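The split test of the smallest p, the within-slide test of Anks1, the shared-component and both-slides tests of the adipocyte markers, the cardiomyocyte marker test and the fit with the adipocyte score as a covariate were chosen after the results were seen.

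Anks1 stood 2.46 higher in PKR2 hearts, with array PKR2 3 at 5.15, off the mean of the other 3 PKR2 arrays by -1.17. Within each shared slide, where slide, scan range and extraction run match, the difference was 1.60 or more. That argues against these as the cause on those slides, each with 1 array per group. The check is weak, since the groups did not overlap and any pairing of arrays would give a positive difference. Anks1 was also chosen by its p over these same arrays. The values also argue against fat content (2.14 with the adipocyte score as a covariate, 95% interval from 1.40, adjusted p = 1). They argue too against a change shared by most features of the region. The 205 other features tested within 5 Mb had a median absolute difference of 0.11, at the 39.1 percentile of windows around other genes. Singly, 5 of the 205 had an unadjusted limma p under 0.05. The nearest, Zfp523, Taf11 and Def6, differed by 0.033, -0.23 and -0.0012, and Ppard, also close by, by 0.63. None of these named features had an unadjusted limma p under 0.05. A change in only a few genes beside Anks1 stays open, since the median cannot show it. Chance cannot be excluded for the smallest p as such: 4 of the 35 splits of the arrays, the real one included, gave one as small as the real 4.77e-06, and the smallest of the other splits was 1.45e-06. Array position is matched with WT 1 alone (3.53), a sequence variant under the single Anks1 probe was not tested, and an effect of the transgene or of where it inserted remains a hypothesis.

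The adipocyte markers were lower in PKR2 hearts on average, with the score of WT 3 (-0.29) off the mean of the other WT arrays by -1.50. Fat tissue carried over in differing amounts is a candidate explanation: a single component took 92.6% of the markers' variance within groups, as varying admixture would give. A fall shared by every PKR2 heart stays open, since the score was 0.73 higher in PKR2 3 than in WT 3 on slide 5 and 0.67 lower on slide 6 (-0.67), with an exact permutation p of 0.143. The brown fat gene Ucp1 was low in PKR2 1 and PKR2 2 (1.58 and 0.30, against 4.26 to 6.16 in WT). Whether the genotype changes the fat around the heart cannot be told apart from dissection with these 8 arrays.

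The hypertrophy list was called higher in PKR2 hearts at the preset correlation with a median of 0.15, and not with an estimated correlation (adjusted p = 0.325). With the adipocyte score as a covariate its median was 0.11 (adjusted p = 0.0223 at the preset correlation), above the bound of 0.1 set beforehand but, by a bootstrap SD of that median over its members of 0.093, brought in only after the value was seen, too close to it to exclude fat content; the same covariate took the mesothelial median from -0.24 to 0.034. The 18 cardiomyocyte markers outside the list had a median of 0.082, between that of the list and 0, so a larger share of cardiomyocyte RNA cannot be told apart from a change of the programme. Chance cannot be excluded for the number of lists: 14 of 35 splits, the real one included, gave at least the real 6 lists, and the highest of the other splits was 11. An effect of the receptor on the hypertrophy programme remains open as a hypothesis.

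For single features the real split gave 0, so all 35 splits give at least as many by construction and the count of splits decides nothing; the highest of the other splits gave 3. That split set WT 1, WT 2, PKR2 1 and PKR2 2, the arrays alone on their slides, against the arrays of the shared slides; with slide as a fixed block the real comparison gave 0 genes. The split of WT 1, WT 4, PKR2 1 and PKR2 4 from the rest puts the 3 arrays of extraction run 2 on 1 side. It had 4215 features at an unadjusted p under 0.05 against 371 in the real one, a structure of the samples that is not their genotype. The split of WT 1, PKR2 1, PKR2 3 and PKR2 4 from the rest had 4082, though it divides those 3 arrays. What underlies this structure was not tested.

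Other single arrays stood apart from the rest of their group, 18 of 188 groups of 4 in all, where chance gives about 1 in 20 (9.4). Among genes, PKR2 1 was lower in Agmo (-0.51 against the mean of the other 3 PKR2 arrays) and in Efemp1 (-0.997), and WT 1 was lower in Efemp1 (-0.90). WT 4 was higher in Cd274 (0.58) and Irgm2 (1.17), and PKR2 4 in Col5a2 (0.26). Among list scores, PKR2 2 was higher in oxidative phosphorylation (0.52), ribosomal proteins (0.42) and the oxidative stress response (0.18). PKR2 4 was lower in the circadian clock (-0.53), PKR2 3 in endothelial cell markers (-0.18), and PKR2 1 higher in skeletal muscle markers (0.44). WT 1 was lower in the unfolded protein response (-0.12) and higher in erythrocyte markers (0.45), WT 3 lower in thymus markers (-0.27), and WT 4 higher in apoptosis and p53 targets (0.049).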

How the results depend on the processing

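The alternatives of normexp after common scaling, slide 6 left out, scan range as a block and the adipocyte score as a covariate were chosen after the results were seen. Under 27 refits Anks1 kept its direction (2.08 to 2.78) and passed in 4. The genes past the threshold numbered 1 (Anks1, higher) with probes above background on all 8 arrays, with slide as random block and with trended robust eBayes; 1 (Fzd2, higher, named after its value was seen, with WT 1 at -6.06 as the lone low array) with array position as a covariate and at position 4 only; 1 at adjusted p under 0.1; 0 to 1 over the fits that leave out 1 array each (1 without PKR2 3); and 0 in the others, with no gene lower in any. At position 4 the lone WT array is assumed to vary like the PKR2 arrays. The number of lists called was 23 under normexp and 21 under normexp after common scaling, 2 with array position as a covariate and at position 4 only, 3 with array weights, 0 with an estimated correlation and 0 by fry, directional or mixed; elsewhere it was 4 to 8, and 4 to 7 over the fits that leave out 1 array each. Under normexp without scaling, the offset of 50 exceeds the 75th percentile of WT 2 (40.9). It also exceeds the median processed signal of WT 2 (4.32), PKR2 4 (8.84), WT 4 (10.4) and PKR2 2 (30.5). This compresses low signals on those arrays, of which WT 2, PKR2 4 and WT 4 were scanned at the single low range. After common scaling 21 lists were still called, so unequal array levels alone need not be the cause. The cause of these and the other shifts was not tested. The calls kept in 27 refits were 24 for hypertrophy, 24 for adipocyte, 20 for mesothelial, 18 for interferon, 12 for Schwann and 10 for ribosomal lists.

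The values below that turned sign are log2 differences. Under normexp these were Tas2r118 -0.64, Prdm10 -0.61, Col12a1 -0.54, Sec16b -0.48, Creb3l3 -0.54, Tnni1 -0.65, Angpt1 -0.15, Oasl1 -0.16, Rpl9 0.19, Rpl10a 0.17, Rps16 0.20, Rps24 0.27, Actb 0.27, Hprt 0.40 and the ribosomal list 0.34. Under normexp after common scaling they were Tas2r118 -0.21, Prdm10 -0.29, Col12a1 -0.17, Sec16b -0.22, Creb3l3 -0.20, Tnni1 -0.41, Rps24 0.075, Actb 0.099, Hprt 0.21 and the ribosomal list 0.15. With array position as a covariate, and alike at position 4 only, they were Trdn 0.18, Angpt1 -0.12, Cav1 0.076, Rpl10a 0.16, Rps24 0.065, Efemp1 0.26, Ckm -0.022, Hprt 0.72 and the ribosomal list 0.18. With slide as fixed block they were Prokr2 0.17, Krt19 0.019, Gapdh -0.0064 and Actb 0.27, and within slide 6 Prokr2 differed by 0.45. With the adipocyte score as a covariate they were Gapdh -0.023, Actb 0.0024 and the mesothelial list 0.034. Actb was 0.0026 and Hprt 0.045 under quantile normalization, Hprt 0.016 with the authors' deposited values and 0.024 with scan range as a block, and Actb 0.14 with the mean of a gene's probes and 0.057 with slide as random block. Leaving out 1 array at a time, Actb ran from -0.25 to 0.063 and Hprt from -0.25 to 0.17. The cause was not tested for any of these.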

Other observations

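Of the tests below, those of the gene lists were planned and the comparison of slide 6 with the other arrays was chosen after the results were seen. Genes of the circadian clock set the arrays of slide 6, WT 4 and PKR2 4, apart from the other 6 arrays, and did so in both genotypes. Of the 19 clock genes tested, 2 were higher and 10 lower on both slide 6 arrays than on any other array, where 9.15% of all features lay outside the other arrays' range on both. Arntl, the activator that drives the clock with Clock, was at -0.76 and -0.19 on WT 4 and PKR2 4 and between -3.77 and -2.74 on the other arrays. Slide 6 minus the other arrays was -1.80 for Per3, -1.56 for Ciart, -1.27 for Per2 and -0.95 for Dbp. Not all targets of the clock moved so: the values were 0.42 for Nr1d1, 0.40 for Bhlhe40 and -0.11 for Nr1d2, none of them outside the range of the other arrays on both slide 6 arrays. The clock list did not differ between genotypes (median 0.0069, adjusted p = 0.948). These genes were named after their values were seen.

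In the thymus marker list (7 genes tested, median 0.26, adjusted p = 0.485), Cd1d1, which encodes a lipid-presenting molecule also made by other cells, passed adjusted over the list alone (-1.16, SE 0.30, adjusted p = 0.0256) and not over all features; it was named after its value was seen. Lymphocyte markers (18 genes) had a median of -0.025, neutrophil and mast cell markers (9 genes) one of 0.28, lung markers (8 genes) one of -0.12 and skeletal muscle markers (11 genes) one of 0.067, with adjusted p of 0.706, 0.638, 0.676 and 0.344. Cell cycle genes (26 genes) had a median of 0.047 and immediate early genes (26 genes) one of -0.025, with adjusted p of 0.587 and 0.836. Smooth muscle and pericyte markers (16 genes) had a median of 0.020 (adjusted p = 0.676). The glucocorticoid and fasting list (18 genes) had a median of -0.043, ion channels and gap junctions (25 genes) one of 0.044 and the unfolded protein response (33 genes) one of -0.039, with adjusted p of 0.689, 0.589 and 0.695. The oxidative stress list (28 genes) had a median of -0.074 and apoptosis and p53 targets (24 genes) one of 0.0044, with adjusted p of 0.485 and 0.836. Median, mean and test differed in sign in 7 of the 38 lists, none of them called.

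The transcripts Lars2 and Rn28s1 varied widely among WT arrays: Lars2 was at 4.30 in WT 4 and between 9.34 and 10.62 in the other WT arrays, and Rn28s1 at -3.50 against 0.82 to 1.94. Near Anks1 on chromosome 17, Pgp differed by -2.98 (SE 2.28) through 1 array, PKR2 1 at -7.57 against 3.50 to 4.36 in the other PKR2 arrays. These 3 genes were named after their values were seen.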
